A study of Mus musculus with 2 samples.

How the data were processed

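The 2 libraries of 1 pooled channel were prepared from sorted OT-I CD8 T cells of 8 mice. One held gene expression and the other held the hashing antibody tags. Per the labels' protocols, the kit was a 10x Genomics 3' single-cell kit with feature barcoding, and the libraries were sequenced with a read 1 of 28 nt, a read 2 of 90 nt and index reads of 10 nt. Per the submitters' processing notes, Cell Ranger was used, with versions 6.0.0 and 6.0.1 both named, and the genome build was mm10. The annotation release, the cell calling settings and the way cells were assigned to mice are not given in the sources used here.

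The deposited files used here are a filtered list of cell barcodes, a list of features with identifier, name and type, and a table with the genotype, vaccine and hashtag of each mouse. They hold text and no measured values. Gene expression counts and hashtag counts were not analysed here, so the planned count tests between arms, the gene list tests, the assignment of cells to mice and the clustering were not run. No cell was assigned to a mouse by any other means.

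Barcodes and features were counted with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. Mice were matched to antibody features by the mouse number in both names. Gene identifiers were looked up without version in GENCODE M21, an annotation of GRCm38, the assembly that mm10 denotes, and all coordinates are 1-based from that annotation. The feature list was not drawn from this release alone, since 50 of its identifiers were not in it. Biotypes, coordinates and overlaps given here may therefore differ from those of the authors' annotation. Before the data were examined, 9 lists of genes and 9 lists of cell type markers were fixed, 137 distinct genes in all, with the rule that list members are reported only as measurable or not where no values can be had. Symbols were matched without regard to case. A gene was called overlapping where any of its exons shared a base with an exon of another gene of the feature list.

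The alternatives tried were distinct barcode sequences, distinct symbols, leaving out predicted genes, and exact symbols. For the barcode set, the number of barcode pairs that differ at 1 base was compared with 100 random sets of the same size. The counting of such pairs was tested on simulated data with planted pairs. No p-value was computed.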

Results

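The samples were OT-I CD8 T cells recovered from the popliteal lymph nodes of C57BL/6 mice and profiled by droplet-based single-cell RNA sequencing with cell hashing. OT-I cells carry a transgenic T cell receptor that recognises an ovalbumin peptide, and the CD45.1 marker separated the transferred cells from those of the recipient. The recipients were either wild type or carried a loxP-flanked Icam1 gene together with CD11c-Cre, a genotype meant to remove ICAM-1 from dendritic cells. Loss of ICAM-1 was not measured here, and recipients described below as lacking it are those of this genotype. Immunisation followed the transfer by 18 h and was given in the footpad, either as ovalbumin coupled to an antibody against the dendritic cell receptor DEC205 with an activating anti-CD40 antibody, or as modified vaccinia Ankara virus encoding ovalbumin (MVA:OVA). T cells were sorted 72 h after immunisation.

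The design had 4 arms of 2 mice each, 8 mice in all. Mice 1 and 2 were wild-type recipients and mice 3 and 4 were recipients lacking ICAM-1 on dendritic cells, all given the anti-DEC205 vaccine. Mice 5 and 6 were wild-type recipients and mice 7 and 8 were recipients lacking dendritic cell ICAM-1, all given MVA:OVA. The arms permit comparisons of the recipient genotypes under each vaccine, the difference between the vaccines, and the interaction of recipient genotype with vaccine. With controls labelled wild type, an effect of ICAM-1 loss could not be told apart from one of CD11c-Cre or the loxP-flanked gene itself. The gene expression and hashtag counts behind these comparisons were not analysed here, so no expression level, fold change, share of cells per arm or test between arms is reported, and nothing below bears on whether the arms differed. The values that follow describe the cells called, the hashtags and the genes that the assay could count.

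The pooled channel held 22430 cell barcodes after the authors' cell calling. Every barcode was 16 bases long and carried the same channel suffix, and no barcode was listed more than once. By the design, all mice were pooled in this 1 channel, so channel and arm were not confounded. The barcode list itself does not show which mice contributed cells. The number of cells from each mouse, the number of droplets with more than 1 hashtag and the depth per cell were not analysed here, and the precision of any per-arm value is unknown.

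Each mouse had its own hashtag of 15 bases. In the anti-DEC205 arms, the wild-type mice carried ACCCACCAGTAAGAC (mouse 1) and GGTCGAGAGCATTCA (mouse 2), and the mice lacking dendritic cell ICAM-1 carried CTTGCCGCATGTCAT (mouse 3) and AAAGCATTCTTCACG (mouse 4). In the MVA:OVA arms, the wild-type mice carried CTTTGTCTTTGTGAG (mouse 5) and TATGCTGCCACGGTA (mouse 6), and the mice lacking dendritic cell ICAM-1 carried GAGTCTGCCAGTATC (mouse 7) and TATAGAACGCCAGGC (mouse 8). Over the 28 pairs of hashtags, the number of mismatched bases ranged from 7 to 14, with a median of 12. The genotype in the mouse table matched the name of the antibody feature for 8 of 8 mice. The feature names of mice 5 to 8 carried the word virus, matching the MVA:OVA vaccine in the table, while those of mice 1 to 4 named no vaccine.

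The feature list held 32293 entries, of which 32285 were genes and 8 were hashing antibodies. A gene called countable or present below was in this list, which does not show that it was detected in these cells. All 32285 gene identifiers were mouse Ensembl identifiers. By the GENCODE M21 annotation, which held 32235 of them (99.8%), 21702 genes were protein coding, 270 were T cell receptor segments or their pseudogenes and 427 were immunoglobulin segments or their pseudogenes. The list included 13 mitochondrial genes. A total of 38 symbols were used by more than 1 identifier, covering 78 genes.

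Icam1, the gene targeted in the CD11c-Cre recipients (mice 3, 4, 7 and 8), was a countable feature (ENSMUSG00000037405, GRCm38 chromosome 9, 21015985 to 21028817, plus strand). The sorted T cells came from the transferred population and not from the Cre-bearing recipient, so Icam1 counts in them would not measure the deletion. Both subunits of LFA-1, the T cell integrin that binds ICAM-1, were also countable, namely Itgal (chromosome 7, 127296260 to 127335138) and Itgb2 (chromosome 10, 77530252 to 77565708). All 13 genes of the adhesion and synapse list were present, Icam2 and Cd226 among them.

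All 17 effector genes were countable, including Gzmb (granzyme B, chromosome 14, 56258838 to 56262260), Prf1 (perforin, chromosome 10, 61297833 to 61304680) and Ifng (interferon gamma, chromosome 10, 118441046 to 118445892). All 13 memory genes were countable, including Il7r (the interleukin-7 receptor, chromosome 15, 9505788 to 9530176) and Tcf7 (the transcription factor TCF-1, chromosome 11, 52252371 to 52283014). The 9 inhibitory genes, 13 T cell receptor activation genes, 12 cell cycle genes, 9 glycolysis genes and 7 migration genes were all present. Of the 10 interferon genes, 9 were present, including Isg15, and Mx1 matched no listed symbol. Aldoa, a glycolytic aldolase, matched 2 gene identifiers.

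Markers of the sorted population and of other cell types in a lymph node were countable as well. All 5 CD8 T cell markers were present, as were the 3 CD4 T cell, 4 B cell, 6 dendritic cell, 4 macrophage and monocyte, 3 NK cell, 3 neutrophil, 4 stromal and endothelial and 2 erythroid markers. Foxp3, the regulatory T cell transcription factor, shared exonic sequence on the same strand with 1 other gene of the feature list, Flicr. Among the 136 matched members of the gene and marker lists, no other had such an overlap, while 21 shared exonic sequence with a gene of the feature list on the opposite strand. For Aldoa, only the identifier ENSMUSG00000030695 was checked for overlaps.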

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

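The number of cell barcodes was 22430 whether counted as listed or as distinct sequences without the suffix. That result was certain, since all barcodes were distinct and shared 1 suffix. The number of genes was 32285 by identifier and 32245 by symbol, and it fell to 21240 without predicted and RIKEN-named genes, by construction of that count. The number of listed genes present was 136 with either way of matching symbols. Other settings for the comparisons between arms (another normalization, no filter on low counts, another assignment of cells to mice, leaving out each mouse, the mouse number as a block, other cluster resolutions and another mitochondrial limit) were not run, because the counts they need were not analysed here. No paired analysis was possible because the columns used hold no values per mouse.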

Other observations

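The cell barcodes were not random strings. The test against random barcodes was planned before its result was seen, and the other tests of this part were chosen afterwards. Base 9 was fixed by base 8 in 22430 of 22430 barcodes, so that only 4 of the 16 possible pairs of bases occurred: A followed by G (5369 barcodes), C by A (5664), G by T (5598) and T by C (5799). The mutual information of these positions was 2.00 bits, against at most 0.03 bits for any other of the 120 pairs of positions. Smaller dependence was present elsewhere. Pairs within positions 1 to 7 reached 0.0284 bits (positions 4 and 5). Those within positions 10 to 16 reached 0.0112 bits (positions 12 and 13). Pairs with 1 position in each of these stretches stayed at or below 0.0006 bits.

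No pair of barcodes differed at a single base (0 pairs). In 100 random sets with the same base shares per position, the number of such pairs ranged from 0 to 8. The observed 0 lay within that range, so the planned test did not exclude chance as the reason for it. The fixed link of bases 8 and 9 shows that the barcodes were not random strings. It does not show why close pairs were lacking. Random barcodes that keep this link held a median of 10 pairs (range 4 to 18 over 100 sets), above the observed 0. Sets drawn from the linear span of the observed barcodes, which filled 28 of 32 binary dimensions against 32 for a random set, held a median of 13 pairs (range 3 to 20). Both models allow fewer strings than the free random sets and, as their draws show, still permit single-base differences. Their medians lay above the 3 pairs of the free random sets. Such models could not account for a lack of close pairs, so no conclusion on its cause is drawn from them. The span keeps only linear constraints on the bases, so a rule of another kind that forbids close pairs was not tested. Whether the manufacturer's barcode list or the authors' barcode correction and cell calling removed close pairs was not tested, and no biological explanation was tested.

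Mx1 was the member of the interferon list that matched no symbol, although GENCODE M21 lists it as a protein-coding gene (ENSMUSG00000000386, GRCm38 chromosome 16, 97447035 to 97462907). The match was by symbol only. Of the 32235 listed identifiers found in GENCODE M21, 31502 carried the same symbol there. The identifiers that share the symbol Aldoa lie next to each other on chromosome 7, ENSMUSG00000030695 at 126795234 to 126800751 and ENSMUSG00000114515 at 126800790 to 126809108.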
